A study of Mus musculus with 4 samples.

How the data were processed

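Bulk RNA sequencing was carried out on 4 mouse liver libraries. Per the labels, 2 came from liver tumours of mice heterozygous for both beta-2 spectrin and Smad3, 1 from normal liver of a mouse of that genotype and 1 from normal liver of a wild type mouse. The submitters' short descriptions read otherwise. They name Elf for tumour 1 and Smad for tumour 2, each with the word Tcell. For both normal libraries they name hepatocytes, for 1 of them together with Smad. The groups follow the genotype and disease labels, so tumours 1 and 2 are treated as replicates of 1 genotype. Total RNA was extracted with TRIZOL and made into libraries with the Illumina TruSeq kit, per the labels' protocols. FastQC, Trimmomatic, TopHat2 2.0.10, HTSeq, DESeq2 and the mouse build mm9 are named in the submitters' processing notes, which give them no role or order. Their settings, including whether strand was used in counting, are not given in the sources used here.

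The deposited values are raw read counts per gene, whole numbers with no normalization, in a separate table for each library. Each table listed 25793 gene symbols, several of them older names (Spnb2 for Sptbn1, Ctgf for Ccn2, Pkm2 for Pkm). Another 5 lines per table named no gene and were left out of library sizes and tests. They counted alignments outside genes (13.6% and 16.4% of all lines in tumours 1 and 2, 24.4% in the normal table labelled double heterozygous and 31.5% in that labelled wild type), alignments that were not unique (45.6%, 42.3%, 51.5% and 30.7% in the same order) and ambiguous reads (at most 0.107%). No coordinates are given because the reference in use (GRCm38, GENCODE M21) is of another build than the counts. That reference served only for sequence: 89.3% of the listed symbols matched it, and for each matched gene the percentage of its 31-mers that also occur in another gene was estimated from a sample of 1 k-mer in 16. Genes above 10% are called genes with shared sequence, and their counts are uncertain.

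Library depth was 11049931 and 13295216 gene counts in tumours 1 and 2, 15950426 in the normal table labelled double heterozygous and 18448621 in that labelled wild type. A count of 0 was read against a floor of 3 counts per library, which is 0.202 and 0.161 CPM in the tumours and 0.329 CPM in the mean normal library on the scale of the fit. For a gene at 0 in a whole group, the bound used the mean floor of that group's libraries. Intervals and floors cover counting error only, since the reads carry no molecular identifiers.

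Before libraries were averaged, their counts were compared. The normal tables shared counts beyond what separate libraries would give, as described with the comparison of the normal livers. Their rounded mean was therefore used as 1 normal library, a choice made after the counts were seen. The fit as designed before the data were examined, with both normal tables as separate libraries, is an alternative. Nothing in the labels says that the tumours came from separate animals. Xist had 0 and 6626 counts in tumours 1 and 2, and the Y-linked genes Ddx3y and Eif2s3y 2208 and 2, and 1149 and 0. The tumours are therefore not repeat libraries of 1 sample, and these counts argue against 1 animal as the source of both. The p-values of genes measure only the spread between these samples.

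Tests were run in R 4.3.3. Tumours and normal liver were compared with edgeR 4.0.16 (TMM scaling, filterByExpr with a minimum count of 10, glmQLFit and glmQLFTest, Benjamini-Hochberg adjusted p under 0.05). This fit has 1 residual degree of freedom per gene, from the tumours, and the normal library is assumed to vary as the tumours do. The common dispersion was 0.442 and the median prior degrees of freedom 3.32. Comparisons with each normal table used the 3 groups in 1 fit of all 4 libraries. CPM values are scaled by TMM. The standard error (SE) of a log2 fold change was derived as the absolute log2 fold change divided by the square root of its F statistic. It is therefore approximate, above all for genes with counts near 0. Comparisons of 1 library with 1 have no replicate check and no test. They used log2 ratios of TMM-scaled CPM with a prior count of 2 over genes with at least 10 CPM in either library, and the medians of gene lists were placed among 10000 random lists of equal size matched on mean expression.

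The 40 gene lists were fixed before the data were examined and tested with camera (limma 3.58.1) with a preset inter-gene correlation of 0.01, adjusted over the lists. With this preset, list p-values measure the spread among genes and not that between the tumours. An estimated correlation and fry were alternatives. With an estimated correlation the list test has only the 1 residual degree of freedom of the fit. It could then hardly pass for any list, so a call lost this way does not show that the list was unchanged. The genes named were fixed by rule at the same time: Spnb2, Smad3, Ctcf, Igf2, H19, Cdkn1c, Tert, Afp, Alb and Myc always. The rule added the 6 largest rises and 6 largest falls with a mean of at least 10 CPM and both tumours on the same side of both normal tables. Of each list, up to 3 changed members with the smallest adjusted p were named, or up to 2 with the highest mean CPM where none changed. In comparisons of 1 library with 1, the 5 largest differences in each direction were named. Other genes named in the text were chosen after their values were seen, which is said where they appear. Some genes that the rule names are not reported here.

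Counts were simulated for the 14468 genes of the comparison of tumours with normal liver, with 200 of the more highly expressed genes changed. The test recovered 0% of 4-fold changes with 0 false calls. It recovered 46.5% of 16-fold changes with 12 false calls and 79% of 64-fold changes with 10 false calls. The data had 1073 calls, and the adjustment is stricter when fewer genes change, so these rates do not give the power in the data. The alternatives were DESeq2 1.42.0, RLE and upper quartile scaling, no filter, a filter at 10 CPM in 2 libraries, a 2-fold threshold with glmTreat, leaving out each library and the 3-group fit. Chosen after the data were seen were the unscaled fits of the tumours against normal liver, further scalings for the lists, and fits without genes with shared sequence. For comparisons of 1 library with 1 the unscaled alternative was designed before, as was the fit with both normal tables separate, which became an alternative afterwards. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for the other steps.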

Results

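Gene expression was measured by RNA sequencing in liver tumours labelled as from mice heterozygous for Spnb2, which encodes the SMAD3 adaptor beta-2 spectrin, and for Smad3, a transcription factor of the TGF-beta pathway. Of the 4 libraries, 2 were labelled tumours of this genotype (tumours 1 and 2), 1 was labelled normal liver of a double heterozygous mouse and 1 normal liver of a wild type mouse. Gene counts ranged from 11049931 in tumour 1 to 18448621 in the library labelled wild type. The comparisons ask how the tumours differed from normal liver, from each normal library alone, and from each other.

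The targeted genes were examined first. Spnb2 stood at 16607 and 19149 counts in tumours 1 and 2, at 3364 in the normal library labelled double heterozygous and at 3549 in that labelled wild type. Smad3 stood at 4521, 2174, 426 and 460 counts in the same order. Between the normal libraries, the log2 ratio of the one labelled double heterozygous to the one labelled wild type was 0.21 for Spnb2 and 0.17 for Smad3. After scaling, neither gene was lower in the library labelled double heterozygous. The normal libraries shared counts beyond sampling, as described below, so this comparison cannot show whether a copy was lost. In the tumours, Spnb2 was at 1073 ± 64.4 CPM (SD, n = 2) against 379 CPM in normal liver and Smad3 at 211 ± 133 CPM against 48.6 CPM. These differences did not pass the test, with log2 fold changes of 1.5 (SE 0.73, edgeR adjusted p = 0.258) and 2.12 (SE 0.87, adjusted p = 0.207).

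**Figure D1:**
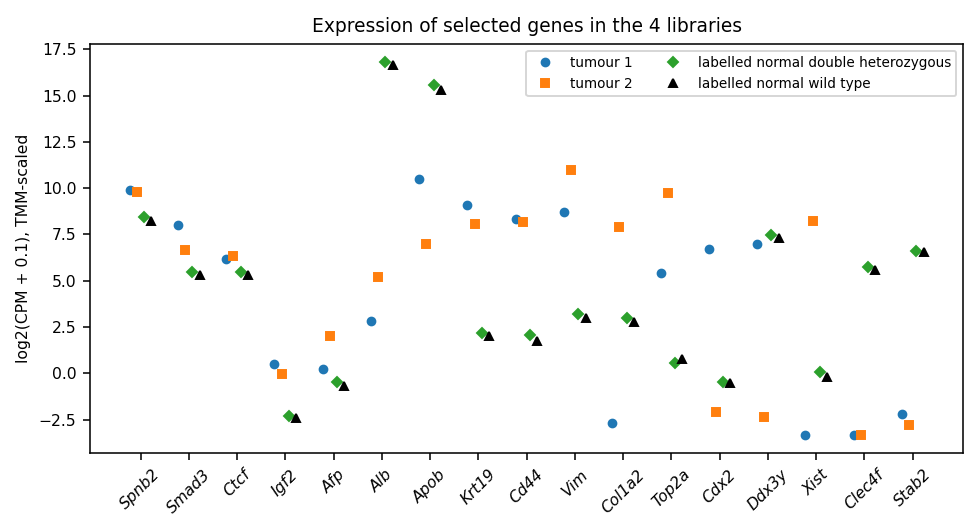
Expression of 17 selected genes in the 4 libraries, as log2 of TMM-scaled CPM plus 0.1 on the vertical axis, with 1 point per library. Spnb2 and Smad3 lie higher in both tumours than in both normal libraries, without passing the test, and Alb and Stab2 lie far lower. Xist, Ddx3y, Cdx2 and Col1a2 differ between the tumours.

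The normal livers were compared to ask what the double heterozygous genotype changes without a tumour. Most liver genes stood at nearly equal levels in both libraries, and none of the 34 plasma protein, 25 cytochrome P450 or 21 bile acid genes compared differed over 2-fold. In other liver lists Ass1, Hadhb, Mup20, Cyp3a41a, Acaca, Idi1 and Fdps, named after their values were seen, were over 2-fold lower in the library labelled double heterozygous, and all have shared sequence. Of 8322 genes, 95.6% lay within 2-fold and 226 differed over 4-fold, 75 of them higher and 151 lower in the library labelled double heterozygous. The lower genes were led by Rpl10, Ppia, Rps2, Rpl3 and Rpl11, ribosomal protein genes apart from the prolyl isomerase gene Ppia, each with 0 counts against 2590, 2074, 1884, 1420 and 1229. The higher ones were led by Gm8203, Gm10288, Gm3934, Gm4332 and Gm8759, predicted genes with 197, 654, 4085, 406 and 279 counts against 0, 4, 42, 3 and 2. Most of the genes over 4-fold share sequence with another gene: of the 205 genes over 4-fold with a matched sequence, 193 (94.1%, exact 95% interval 90.0 to 96.9) had shared sequence, against 22.5% of all 8148 matched genes compared. In the list of 14 glycolysis genes, 5 were over 2-fold lower, among them Gapdh, named after its values were seen, which has shared sequence. The median log2 ratio of this list, with such genes included, was -0.46, and the cytochrome P450 median was -0.03. Both medians lay at percentile 0 of matched random lists, and those of the male-biased and urea cycle lists (0.00 and 0.09) at percentiles 0.28 and 1.02. At the other end were TGF-beta pathway components (0.17) and immediate early genes (0.22), both at percentile 99.8, and Kupffer cell (0.18), antigen presentation (0.20), TGF-beta target (0.18), epithelial (0.19), IGF axis (0.21), acinar (0.18), fibroblast (0.19) and imprinted (0.17) lists, at 95.5 to 98.7. These percentiles hold for these libraries only. The counts of the normal libraries were closer than sampling allows, as described next, so the percentiles cannot tell genotype from different processing of the same reads.

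The counts of the normal libraries were closer than sampling allows. Among the 2483 genes with a mean count of 1 to 5, 56.9% had equal counts in both, against 21.8% expected of independent libraries of these depths, and the library labelled wild type had the lower count in 3.66% against 26.7%. The median chi-square of a gene was 0.0887 in this range, where sampling noise gives 0.455, and at a mean count of 1000 to 10000 it was 4.43. The tumours, by contrast, had equal counts in 13.5% of such genes. Low counts thus differed by less than the sampling noise, and the normal libraries were counted as 1 sample by taking their mean. For genes with shared sequence that mean is uncertain.

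**Figure D2:**
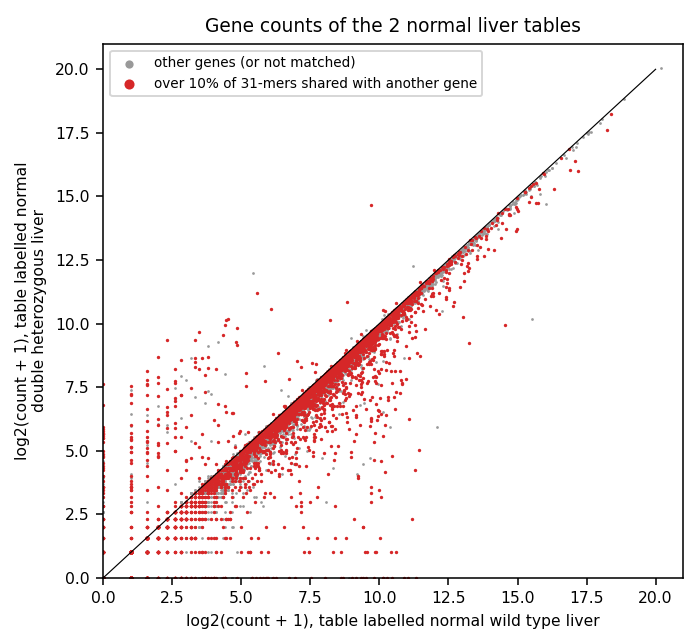
Gene counts of the normal tables, as log2 of the count plus 1, with the table labelled wild type on the horizontal and that labelled double heterozygous on the vertical axis, and 1 point per gene. Most genes follow the diagonal, and genes with over 10% of their 31-mers in another gene, in red, make up 94.1% of the sequence-matched genes compared that differ over 4-fold.

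Against this normal liver, the tumours held few transcripts of hepatocyte function. Among 34 plasma protein genes, 29 fell and 0 rose (33 fell when adjusted over the list alone). Albumin, the main plasma protein, dropped from 1083426 and 1194814 counts in the normal libraries to 123 and 807 in the tumours (log2 fold change -12.24, SE 2.09, edgeR adjusted p = 0.0479). That call missed the threshold against either normal library alone (adjusted p = 0.0558 for that labelled double heterozygous and 0.0513 for that labelled wild type) and without genes with shared sequence (0.0574). The apolipoprotein genes Apoc3 and Apoh were at 1905 and 3862 CPM in normal liver and at 3 and 3, and 3 and 2, counts in the tumours. Apoa4, with shared sequence, was at 532 CPM against 0 and 1 counts. Of the members that did not pass, Apob and C3, chosen after their values were seen, kept 25518 and 31048 counts in tumour 1 and 2795 and 8024 in tumour 2. The list median was -13.29 on the log2 scale, and -13.27 with genes at 0 in a group taken at their bound.

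Metabolic genes of the hepatocyte followed. Among 25 cytochrome P450 genes 22 fell (24 adjusted over the list alone), with Cyp2c29 at 4365 CPM in normal liver and at 8 and 5 counts in the tumours. Cyp2a5 and Cyp2a12, both with shared sequence, had 1 and 4, and 1 and 1, counts in the tumours against 2537 and 1564 CPM. In the urea cycle and amino acid list 20 of 24 fell (23 adjusted over the list alone), among them Tat and Hal, which break down tyrosine and histidine and had 2 and 2, and 3 and 2, tumour counts against 4036 and 323 CPM. For bile acid synthesis and transport it was 17 of 21 (21 adjusted over the list alone), with Cyp7a1, the rate-limiting enzyme, at 1362 CPM against 1 count in each tumour, Cyp8b1 at 938 CPM against 5 and 2 counts, and Baat at 238 CPM against 2 and 2. Among 10 gluconeogenesis genes 5 fell (10 adjusted over the list alone): Pck1 (log2 fold change -13.96, SE 1.14, adjusted p = 0.0182), G6pc, Tat and, named after their values were seen, Fbp1 and Slc37a4. Fatty acid oxidation had 10 of 24 lower (22 adjusted over the list alone), with Bdh1 at -7.45 (SE 0.61, adjusted p = 0.0182) and Acaa1b at -10.08 (SE 0.77). Bdh1 and Acaa1b have shared sequence. Of 19 liver transcription factors 5 fell (14 adjusted over the list alone): Onecut1 at -8.24 (SE 0.84), Prox1 at -6.19 (SE 0.86), Nr1i3 at 0 counts in both tumours and at least 1903-fold lower, and Foxa1 and Ppara, named after their values were seen. Onecut1 and Nr1i3 have shared sequence. No member of these 7 lists, plasma proteins included, rose. Camera called all 7 lower (adjusted p from 1.23e-27 to 1.38e-08), with none of the calls kept at adjusted p = 0.513 with an estimated correlation. That alternative has 1 residual degree of freedom, so its loss of the calls cannot decide whether correlation between genes produced them. Transcripts of endothelial cells (Stab2 at 2 and 1 counts) and Kupffer cells (Clec4f at 0 and 0) were low in the same tumour libraries.

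By fitted log2 fold change, the largest falls reported here were of genes with 0 counts in both tumours, whose folds have a lower bound only. Genes with a few tumour counts may have fallen as far, such as Tat (-14.93), Cyp2d9 (-14.89, shared sequence) and Apoh (-14.55). Cyp2d10, a cytochrome P450, was at least 7764-fold lower, the complement gene C8b at least 7249-fold, the coagulation factor gene F12 at least 7141-fold, Bhmt, of methionine metabolism, at least 7046-fold and the major urinary protein gene Mup21 at least 6253-fold. Adjusted p values lay between 0.022 and 0.0223. Cyp2d10, Bhmt and Mup21 have shared sequence (49.6%, 31.9% and 26.8% of their 31-mers), and Bhmt and Mup21 differed between the normal libraries, with 7867 against 15478 and 6416 against 14300 counts.

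By the same order, the largest rises were of genes with 0 counts in both normal libraries, again with a lower bound only, and several of the bounds lie below the folds of S100a6 (log2 fold change 10.06) and Sox4 (9.59, shared sequence). Flnc, which encodes the actin crosslinker filamin C, reached 331 ± 91.1 CPM (SD, n = 2) and was at least 1007-fold higher. The cystine transporter gene Slc7a11 reached 159 ± 35.6 CPM (at least 482-fold), the Wnt ligand gene Wnt7b 107 ± 6.71 CPM (at least 326-fold), the calcium channel subunit gene Cacnb3 94.5 ± 12.1 CPM (at least 287-fold), the cadherin gene Cdh6 91.1 ± 22.9 CPM (at least 277-fold) and the heparan sulfate sulfotransferase gene Hs6st2 72.8 ± 48.6 CPM (at least 221-fold). Their edgeR adjusted p lay between 0.0205 and 0.0363.

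Some tumour marker and bile duct genes rose. Of 19 oncofetal and tumour marker genes 7 rose and 0 fell (10 rose adjusted over the list alone), with Cd44, a hyaluronan receptor, 87.0-fold higher (log2 fold change 6.45, SE 0.82, adjusted p = 0.0294), the transcription factor gene Sox4 at 9.59 (SE 1.34, shared sequence) and the aldo-keto reductase gene Akr1b8 at 7.53 (SE 1.06, shared sequence). Afp, the classical fetal liver marker, did not pass, with 19 and 85 counts against 6 and 6 (adjusted p = 0.450). Of 15 bile duct genes 4 rose (6 adjusted over the list alone). They were the keratin genes Krt7, at 223 ± 17.8 CPM against 0.767 CPM (log2 fold change 8.17, SE 0.86, adjusted p = 0.0227), and Krt19 (6.63, SE 1.06), osteopontin Spp1 (5.77, SE 0.96, shared sequence) and, named after its values were seen, Tspan8. Krt7 and Krt19 also rose in the list of 18 epithelial adhesion genes, where the claudin gene Cldn1 fell (-4.91, SE 0.74), as did Cldn3, named after its values were seen; adjusted over the list alone 7 rose and 3 fell. Camera called the marker list (adjusted p = 6.02e-07) and the bile duct list (0.0027) higher, and not the epithelial list (0.0582). With an estimated correlation the adjusted p was 0.513 for the markers and 0.531 for the bile duct list.

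Mesenchymal and TGF-beta target genes also included large rises. In the mesenchymal list 3 of 20 rose (6 adjusted over the list alone): S100a6, a calcium-binding protein gene, at 1063 ± 220 CPM against 0.986 CPM (log2 fold change 10.06, SE 1.16, adjusted p = 0.0258), the urokinase receptor gene Plaur (7.14, SE 1.00) and the receptor kinase gene Axl (5.32, SE 0.83). Of 28 TGF-beta target genes 6 rose and 0 fell (9 rose adjusted over the list alone), among them Ctgf, at 243 ± 4.62 CPM against 2.3 CPM (6.72, SE 0.79, adjusted p = 0.0263, shared sequence), and Pmepa1 (6.47, SE 0.84). Camera called both lists higher (adjusted p = 0.00128 and 4.04e-05). These calls were lost at adjusted p = 0.513 for the mesenchymal and 0.531 for the TGF-beta target list with an estimated correlation. Among 38 components of the pathway 3 rose, Ltbp3 (7.28, SE 0.90), the ligand gene Tgfb2 (8.19, SE 1.22) and, named after its values were seen, Tgfb3. The activin subunit gene Inhbe fell, at least 438-fold. The same counts held adjusted over the list alone, and the list was not called (adjusted p = 0.229). In the list of 24 fibroblast and collagen genes Col4a2 rose (3.76, SE 0.66) and Reln fell (-10.24, SE 1.24), with 2 in each direction adjusted over the list alone and no call for the list (adjusted p = 0.308). Col4a2 was past the threshold at adjusted p = 0.0494, and at 0.0514 without the normal library labelled wild type.

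Sugar and lipid genes moved in both directions. Of 22 glycolysis genes 5 rose (7 adjusted over the list alone): Hk1, a hexokinase gene of most non-liver tissues (66.3-fold, log2 fold change 6.04, SE 0.75, adjusted p = 0.0278), the lactate exporter gene Slc16a3 (6.81, SE 0.93), the pyruvate kinase gene Pkm2 (6.41, SE 0.94, shared sequence) and, named after their values were seen, Hk2 and Eno2. The member called lower was Gapdh (2 adjusted over the list alone), also named after its values were seen, a gene with shared sequence that had 66 and 160 counts in the tumours, 18 in the normal library labelled double heterozygous and 2530 in that labelled wild type. Against the former alone it was not lower (log2 fold change 1.56, adjusted p = 0.253). In the lipogenesis list 6 of 20 fell (10 adjusted over the list alone), including Thrsp, with 349 CPM in normal liver and 1 count in each tumour, Dgat2 (-7.62, SE 0.80) and Acacb (-8.38, SE 1.05), and Scd2, named after its values were seen, rose (1 adjusted over the list alone). Of 19 cholesterol synthesis genes Dhcr7 fell (-3.13, SE 0.54, adjusted p = 0.0486), a call lost under upper quartile scaling (0.0521) and without scaling (0.106), and 11 fell adjusted over the list alone. Camera called glycolysis higher (adjusted p = 0.0067) and lipogenesis (3.22e-05) and cholesterol synthesis (4.04e-05) lower. With an estimated correlation the adjusted p was 0.513, 0.513 and 0.617.

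Most cell cycle genes were higher in both tumours, but unequally so, and few passed the test. Of 30 G2/M genes 29 were higher in both tumours than in normal liver and 0 passed the test, by edgeR over all genes or adjusted over the list alone. At an unadjusted p under 0.05, 15 were higher and 0 lower, and DESeq2 called 28 higher. Top2a, the topoisomerase of dividing cells, was at 50.7 and 1009 CPM in tumours 1 and 2 against 1.75 CPM (adjusted p = 0.143), and Mki67 at 26.8 and 596 CPM against 2.63 CPM (adjusted p = 0.175). Of 26 G1/S genes 21 were higher in both tumours, and the cyclin D genes Ccnd1 (40.5-fold, log2 fold change 5.32, SE 0.88, adjusted p = 0.0456, shared sequence) and Ccnd2 (22.4-fold, 4.50, SE 0.71, adjusted p = 0.0424) rose, with the same 2 adjusted over the list alone. Camera called the G2/M (adjusted p = 3.67e-06) and G1/S (1.57e-05) lists higher; the adjusted p was 0.62 and 0.617 with an estimated correlation. Of 20 p53 target genes Phlda3 rose (8.52, SE 0.90, adjusted p = 0.0229) and 9 rose adjusted over the list alone. That list was called (adjusted p = 0.000214) and lost its call at adjusted p = 0.539 with an estimated correlation. Myc, a driver of growth, was at 53.9 ± 22.0 CPM against 48.9 CPM (log2 fold change 0.14, SE 0.65, adjusted p = 0.905).

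Imprinted, insulin-like growth factor (IGF) and chromatin lists were not called. Igf2 was at 23 and 19 counts against 1 and 1 (adjusted p = 0.355, shared sequence), Cdkn1c at 13 and 7 against 3 and 4 (0.890, shared sequence) and H19 at 8 and 4 against 10 and 10, too few to be tested. Of 31 imprinted genes 0 passed by edgeR, over all genes or adjusted over the list alone; Gnas, with shared sequence, stood at 581 ± 35.6 CPM against 424 CPM and Cd81 at 511 ± 119 CPM against 454 CPM. At an unadjusted p under 0.05, 2 imprinted genes were higher and 7 lower, the same counts as DESeq2 called. The imprinted list had a median of 0.50, a mean of -0.10 and a camera test directed lower (adjusted p = 0.701). Ctcf, which encodes the insulator-binding protein, was at 89.5 ± 7.22 CPM against 47.8 CPM (adjusted p = 0.347). Among the 12 CTCF and cohesin genes, Stag2 and Wapal had log2 fold changes of -0.22 and -0.12. Among the 16 telomerase and shelterin genes, Tert, the catalytic subunit, was at 5.95 ± 0.445 CPM against 18.6 CPM (log2 fold change -1.65, SE 0.74, adjusted p = 0.232), and Tep1 and Nop10 had -0.15 and 0.73. In both lists 0 genes passed, over all genes or adjusted over the list alone, and neither list was called (adjusted p = 0.308 and 0.465). At an unadjusted p under 0.05, and by DESeq2, 1 CTCF and cohesin gene was higher and 0 telomerase genes differed. Of 17 IGF axis genes 3 fell, Ghr, the growth hormone receptor gene (-6.37, SE 0.72, adjusted p = 0.0255), and Igfbp1 and Igfals, at 461 and 454 CPM in normal liver and at 0 and 1, and 1 and 1, counts in the tumours. Igf1r, named after its values were seen, rose, and adjusted over the list alone 2 rose and 5 fell. The IGF list was not called (adjusted p = 0.0704), but was called lower with upper quartile scaling (0.038), without scaling (0.00703), at 10 CPM in 2 libraries (0.0153), without the normal library labelled wild type (0.0494) and without genes with shared sequence (0.0222). Its median of -1.19 became 0.20 without TMM scaling. Of 20 Wnt target genes Ccnd1 rose and Slc1a2 (-4.86, SE 0.59) and Rhbg (at least 142-fold lower, shared sequence) fell, with 1 and 3 adjusted over the list alone. Its median of 0.28 and mean of 0.58 were opposite in sign to its camera direction (adjusted p = 0.416), and the list was called lower at 10 CPM in 2 libraries (0.0496).

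Transcripts of endothelial, Kupffer, red blood, acinar, adipocyte and B cell lists were low in the tumours, while the bile duct list had medians of 2.50 and 2.35 in tumours 1 and 2 over normal liver and the fibroblast and collagen list -0.13 and 3.68. Of 21 endothelial genes 4 fell and 0 rose (16 fell adjusted over the list alone): the sinusoidal receptor gene Stab2, at 112 CPM in normal liver and 2 and 1 counts in the tumours, Tie1, at 38.3 CPM and 2 and 1 counts, the growth factor receptor gene Kdr (-8.00, SE 1.14, adjusted p = 0.0358) and, named after its values were seen, Clec4g. Of 21 Kupffer cell and macrophage genes Clec4f, Cd5l and Cd163 fell, each with 0 counts in both tumours and at least 321-fold, 194-fold and 173-fold lower, and 8 fell adjusted over the list alone. Among 6 red blood cell genes Alas2, Hba-a1 and Hbb-b1 fell (4 adjusted over the list alone), with 279, 271 and 222 counts in the normal library labelled double heterozygous and at most 1 in either tumour. Alas2 and Hba-a1 have shared sequence, and Hbb-b1 was not matched to a sequence. Among 13 pancreatic acinar genes 5 fell (13 adjusted over the list alone): Pnlip, Ctrb1 and Cela2a (shared sequence), at least 250-fold, 182-fold and 164-fold lower, and, named after their values were seen, Cel and Cpa1. Of 7 adipocyte genes Car3 (-12.75, SE 1.40), Plin4 (-6.56, SE 0.63) and Pck1 fell, as they did adjusted over the list alone; liver itself expresses Car3 and Pck1. Camera called these lists lower (adjusted p from 5.79e-09 to 0.00343), as well as the 5 B cell genes (0.0359), of which 0 passed over all genes or adjusted over the list alone. In the latter, Ms4a1 was at 0 counts in both tumours against 13 and 19 and Blk at 0 and 54 counts against 3 and 3. With an estimated correlation the adjusted p was 0.617 for Kupffer cells and 0.513 for the endothelial, red blood cell, acinar, adipocyte and B cell lists. The 6 T and NK cell genes (Tcf7 at 8 and 92 counts against 15 and 19, Zap70 at 0 and 9 against 30 and 37) and 5 neutrophil genes (Mmp8 at 53 and 0 counts against 0 and 0, S100a9 at 9 and 14 against 8 and 9) had 0 changed members over all genes or adjusted over the list alone, and neither list was called (adjusted p = 0.342 and 0.986). Of the B cell, T and NK cell and neutrophil genes, 1 T and NK cell gene was lower at an unadjusted p under 0.05, and DESeq2 called 0. The median of the T and NK list, -0.49, was 0.87 without TMM scaling.

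Response genes and sex-biased genes made up the rest of the lists. Of 20 acute phase genes 10 fell and 2 rose (15 and 3 adjusted over the list alone), with Itih3 (-12.99, SE 0.94, adjusted p = 0.0182) lower, the hepcidin gene Hamp, with shared sequence, at 479 CPM against 1 count in each tumour, and Fgl1 at 282 CPM against 1 and 4 counts. The risen members, named after their values were seen, were the chemokine gene Cxcl1 and the interleukin-1 antagonist gene Il1rn. Of 15 antigen presentation genes H2-K1 (-4.98, SE 0.70, shared sequence) and Nlrc5 (-5.21, SE 0.81) fell, and 8 adjusted over the list alone. Of 21 interferon response genes Ifit2 rose (4.63, SE 0.79, adjusted p = 0.0478), a call that ended at 0.0524 without the normal library labelled wild type; 1 rose and 1 fell adjusted over the list alone. Of 18 immediate early and heat shock genes Ier3 rose (7.0, SE 0.79) and Hspa1b fell (-4.26, SE 0.54, shared sequence), with 3 and 1 adjusted over the list alone. Male-biased liver genes fell in 13 of 15 cases (15 adjusted over the list alone), with Cyp2d9, Slco1a1 and C6 at 3026, 1998 and 1174 CPM in normal liver and at 2 and 1, 5 and 3, and 1 and 2 tumour counts, and Cyp2d9 has shared sequence. Female-biased genes fell in 4 of 11 cases (8 lower and 1 higher adjusted over the list alone): Cyp4a10, with shared sequence, and Fmo2 had 0 and 1 tumour counts against 458 and 53.2 CPM, Acot3 was at least 204-fold lower with shared sequence, and Cyp17a1 was named after its values were seen. Camera called the acute phase (adjusted p = 7.85e-06), antigen presentation (5.91e-05), male-biased (1e-14) and female-biased (1.58e-05) lists lower and the immediate early list higher (0.0492). The last call ended without the normal library labelled wild type (0.0651), with RLE scaling (0.0503) and at 10 CPM in 2 libraries (0.0679). All 5 calls were lost at adjusted p = 0.513 with an estimated correlation. The interferon list was not called (adjusted p = 0.694), nor were the 5 Y-linked and Xist genes (0.481), of which 0 passed over all genes or adjusted over the list alone; the latter list had a median of -0.76 and a mean of 0.70, and a median of 0.58 without TMM scaling. Of these 5, 0 had an unadjusted p under 0.05 and DESeq2 called 0.

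**Figure D3:**
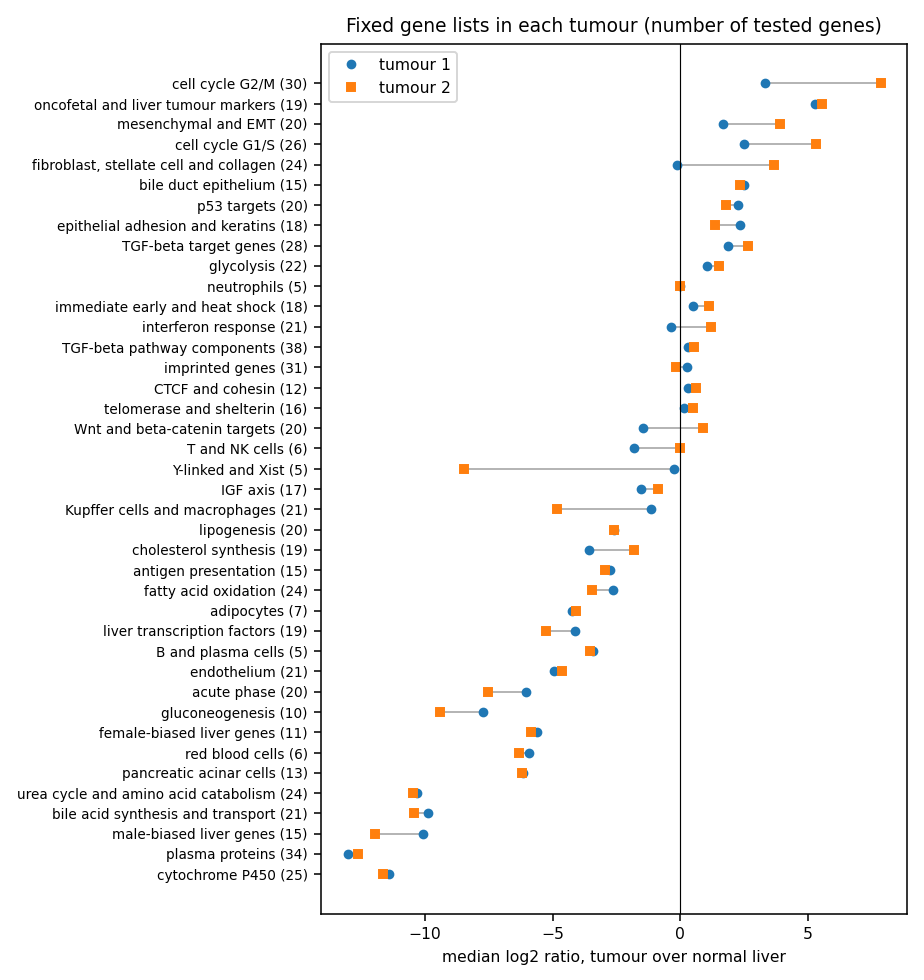
Median log2 ratio of each of the 40 gene lists in tumour 1 (circles) and tumour 2 (squares) over normal liver, with the number of tested genes in brackets and a line joining the tumours. Liver function lists lie far below 0 in both tumours, down to -13.03 and -12.61 for plasma proteins, and the G2/M list lies at 3.32 in tumour 1 and 7.85 in tumour 2.

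In all, edgeR's quasi-likelihood test called 1073 of 14468 genes, 322 higher and 751 lower, and both tumours lay on the called side for every one of them. Camera called 28 of the 40 lists, 9 higher and 19 lower, and 0 with an estimated correlation. With 1 residual degree of freedom, that alternative could hardly call any list. Fry, which tests a list by itself, called 2, the urea cycle and acinar lists. The balance of directions depended on scaling: TMM left the median of all genes at 0.19 on the log2 scale, and without it the median was 1.56 and 635 genes were called higher and 472 lower. Without that scaling 14 named falls lost their call (adjusted p from 0.0527 to 0.106), among them Kdr, Cd163, Hbb-b1 and Dhcr7. Against a 2-fold threshold Alb, Dhcr7, Ccnd1, Ccnd2, Col4a2, Spp1 and Ifit2 did (0.0501 to 0.0673).

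Each normal library was then set against the tumours alone. Against the one labelled double heterozygous, which asks about the tumour at a single labelled genotype, S100a6 and Krt7 rose by log2 fold changes of 9.90 and 8.22, and Pck1 and Dgat2 fell, at -14.06 and -7.75 (edgeR adjusted p from 0.0189 to 0.0225). Of the fixed lists, 27 of 34 plasma protein genes, 22 of 25 cytochrome P450 genes and 18 of 21 bile acid genes fell, 8 of 21 endothelial genes fell and 8 of 19 tumour markers rose. Alb, at -12.33, did not pass (adjusted p = 0.0558), and neither did Spnb2 (1.38, adjusted p = 0.292) or Smad3 (2.01, 0.214). The test called 1152 of 14635 genes, 320 higher and 832 lower. This fit assumes that the lone normal library varies as the tumours do, and which of the normal labels the shared counts belong to is open.

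Against the library labelled wild type, where tumour and labelled genotype differ together, the same 4 genes had log2 fold changes of 10.18 and 8.09 for S100a6 and Krt7 and -13.90 and -7.54 for Pck1 and Dgat2 (adjusted p from 0.0183 to 0.0212). Spnb2 was at 1.58 (adjusted p = 0.236) and Smad3 at 2.18 (0.185). Rpl10, Ppia and Gapdh, all genes with shared sequence and named here after their values were seen, were called lower in this comparison (-11.88, -10.42 and -5.29) and had values of 2.84, 3.98 and 1.56 against the other normal library, none past the threshold. The test called 1419 genes, 450 higher and 969 lower. Because both comparisons use the same tumours and the normal libraries share counts, they are not independent, and the difference between them was not tested.

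The tumours were compared with each other to show the spread within the only group with 2 libraries. Tumour 2 had far more transcripts of dividing cells and of collagen: 29 of 29 G2/M genes and 19 of 26 G1/S genes were over 4-fold higher than in tumour 1, with list medians of 4.48 and 2.61, as were 13 of 16 fibroblast and collagen genes, with a median of 4.77. Col1a2, Col6a3, Ccdc80 and Grem1, genes of collagens, extracellular matrix and a BMP antagonist, had 5230, 3505, 4682 and 872 counts in tumour 2 and 1, 1, 4 and 0 in tumour 1. Tumour 1 had 1814 counts of the intestinal transcription factor gene Cdx2 and 901 of the retinoic acid enzyme gene Aldh1a3, against 3 and 1 in tumour 2, and 899 against 1 of AI747448, which has shared sequence. Xist, the RNA of X inactivation (shared sequence), had 0 counts in tumour 1 and 6626 in tumour 2, while the Y-linked genes Ddx3y and Eif2s3y had 2208 and 1149 counts in tumour 1 and 2 and 0 in tumour 2.

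Further lists separated the tumours. Cholesterol synthesis (median log2 ratio of tumour 2 to tumour 1 of 1.44), Wnt targets (1.71), telomerase and shelterin (1.01) and TGF-beta targets (0.79) lay higher in tumour 2, at percentiles of 99.8 to 100 of matched random lists. Plasma proteins (-2.0), tumour markers (-1.16), bile duct (-1.07), epithelial adhesion (-0.97), p53 targets (-0.78), liver transcription factors (-0.73), imprinted genes (-0.66), acute phase genes (-0.79) and fatty acid oxidation (-0.65) lay lower, at percentiles of 0 to 1.32. These medians cover members at 10 CPM or more in either tumour, 9 of 34 for plasma proteins and 14 of 19 for tumour markers. Over all tested members, the medians of tumours 1 and 2 over normal liver were -13.03 and -12.61 for plasma proteins and 5.26 and 5.53 for tumour markers, which puts tumour 2 higher in both. Most plasma protein members lay under 10 CPM in both tumours, so the medians of that list compare counts near the floor. Of the members compared, 6 plasma protein genes were over 2-fold lower and 1 higher in tumour 2, and 8 tumour markers lower and 2 higher. In total 886 of 9193 genes differed over 4-fold, 609 higher and 277 lower in tumour 2, and 72.6% lay within 2-fold. These are differences between 2 libraries, with no replicate check.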

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

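All tests in this part were chosen after the results were seen. Of the alignments, 51.5% were not unique in the normal table labelled double heterozygous and 30.7% in that labelled wild type, a signal on lines of the tables that name no gene and enter no comparison. In the tumours the shares were 45.6% and 42.3%.

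The near-equal counts of the normal tables were weighed as 2 similar livers sequenced separately or as 1 library in both tables. Separate sequencing would put the lower count in the table labelled wild type for 26.7% of genes with a mean count of 1 to 5, and the share was 3.66%, which argues against it. Equal counts in 56.9% of those genes, against 21.8% for independent libraries, are consistent with both tables coming from reads of 1 library processed in different ways. For the genes that do differ over 4-fold between the tables, 94.1% having shared sequence, against 22.5% of all compared, is consistent with reads that fit several genes having been placed differently. Which label the shared reads belong to, and whether genotype adds any difference, stays open, and no biological explanation was tested.

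The calls between tumours and normal liver could come from the same difference in read placement, since for some genes the tumours resemble the table labelled double heterozygous (Rpl10 had 1, 1, 0 and 2590 counts in tumours 1 and 2 and the normal tables labelled double heterozygous and wild type). In the same order, 24, 16, 34 and 5 of 92 ribosomal protein genes had under 10 counts, and predicted Gm genes together held 11566, 14810, 7363 and 4623 CPM before TMM scaling, both higher than in the table labelled wild type. The ribosomal protein genes together, at 7361, 10698, 1120 and 4414 CPM, lay above that table in the tumours and below it in the table labelled double heterozygous. Of the 1073 calls, 251 have shared sequence (24.0% of matched calls, against 23.0% of all matched genes tested), 109 ended without the table labelled wild type, and 29.1% met either condition, which argues against read placement as the main source. Of the 109, 93 were still tested then, with a median absolute change of 0.14 in log2 fold change, and 20 of them moved over 2-fold. Of all 1057 calls still tested, 1049 kept their direction and 28 moved over 2-fold. Read placement stays open for those that reversed or moved over 2-fold and for the calls no longer tested.

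Low transcripts of red blood, endothelial, Kupffer and B cells in both tumours were weighed as a matter of depth, of cell content and of a word in the submitters' descriptions of the tumours that could be read as T cells. T cells are argued against, since the highest of Cd3d, Cd3e, Cd3g, Cd247 and Lck was 0.514 CPM in either tumour. Lower depth is argued against too, since 85.7% of the 42 genes lower in both tumours would have over 30 counts in each tumour at the normal level. Cell content stays open and was not tested: of the fibroblast and collagen genes 12 were higher and 5 lower in both tumours, and of the neutrophil genes 2 and 2. Whether the low lists reflect the tumours themselves or how the material was taken stays open too.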

How the results depend on the processing

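Unscaled fits of tumours against normal liver and fits without genes with shared sequence were chosen after the data were seen, and the fit with both normal tables separate, designed before, became an alternative then. The 1073 genes changed between tumours and normal liver became 3409 with DESeq2 (1666 higher, 1743 lower), 2286 without a filter, 2463 at 10 CPM in 2 libraries (1061 and 1402), 2410 in the 3-group fit (1112 and 1298) and 6215 with both normal tables separate (3058 and 3157), where tables that share counts enter as separate libraries and residual degrees of freedom rise to 2. Of the 1073, 322 were higher and 751 lower, against 903 and 1383 without a filter and 635 and 472 (57.4% higher) unscaled. RLE, upper quartile scaling, glmTreat, the unscaled fit and leaving out shared sequence gave 1352, 1101, 852, 1107 and 812 genes, and leaving out a normal table gave 973 to 1260. Against the normal library labelled double heterozygous, 1152 genes became 3144, 2374 and 2474 with DESeq2, no filter and 10 CPM, and against that labelled wild type 1419 became 3387, 2625 and 2615. The share of higher calls moved from 27.8% to 44.8% with DESeq2 and 56.1% unscaled in the former and from 31.7% to 46.9% and 59.3% in the latter. The 226 genes over 4-fold between normal libraries became 417 at 1 CPM, 104 at 50 CPM and 12 without shared sequence, and the 886 between tumours 1827 at 1 CPM and 332 at 50 CPM. The 28 lists became 0 with an estimated correlation and 2 with fry, and stayed between 25 and 29 otherwise. The cause of these shifts was not tested. Of values for single genes, 1331 with an adjusted p kept direction and side of the threshold, 25 lost their call and 11 gained one. With a tumour left out there is no test, and the ratio of the other tumour to normal liver was set against the fitted log2 fold change. It lay within 1 SD of the tumours' ratios for 89 values and further away for 147. The ratios used a prior count of 2 that the fit did not, so these counts do not measure stability. Reversal was looked for only among called genes, where both tumours lay on the called side, so none could be found. Leaving out a tumour leaves 1 library against 1 with no residual degree of freedom, so no count was made. No paired analysis was possible because the groups compared share fewer than 2 replicate numbers. In simulated counts with 200 genes changed, 4-fold changes were not recovered (0%). Far more genes were called in the data, so that rate does not give the power there.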

Other observations

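Some single genes, chosen after their values were seen, had large or unequal counts in the tumours. They were not tested together as a list, though most are members of the fixed lists. The neutrophil chemokine gene Cxcl5 had 57548 and 14391 counts in tumours 1 and 2 and 4 and 3 in the normal tables (log2 fold change 12.34, edgeR adjusted p = 0.052), Lcn2 had 22646 and 4038 against 72 and 81 (adjusted p = 0.111) and Saa3 10392 and 263 against 120 and 151 (adjusted p = 0.315). Cxcl1, another chemokine gene, rose, with 4633 and 3704 counts against 52 and 72 (5.23, adjusted p = 0.041). Vim, of mesenchymal cells, had 7417 and 43694 counts against 88 and 91 (adjusted p = 0.082). The epithelial gene Epcam had 356 counts in tumour 1 and 4 in tumour 2, and the imprinted gene Ndn 534 and 1.

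Pancreatic enzyme transcripts were present in both normal tables at nearly equal counts: Pnlip at 399 and 430, Cela2a at 263 and 280 and Cpa1 at 190 and 196 in the tables labelled double heterozygous and wild type. Because these tables share counts, this does not show the transcripts in separate livers.

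The following hypothesis was tested after the result was seen. Male-biased liver genes may have fallen because tumour 2, with Xist and without Y-linked transcripts, came from a female animal while the other libraries have Y-linked transcripts. The list median in tumour 1, which has Y-linked transcripts, was -10.09 relative to normal liver, so a sex difference does not account for the fall there.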
